A study of Mus musculus with 20 samples.

How the data were processed

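The data were 20 Affymetrix mouse expression arrays, each hybridised with the amplified cDNA of 1 inner cell mass cell. Per the labels' protocols, each cell was lysed, its cDNA was synthesised and amplified by PCR without purification (the method is named V1V3 in the series design), and biotin-labelled cRNA was prepared by the one-cycle Affymetrix protocol. The deposited values were probe set intensity on a linear scale, from 1 to 26616, with 10.1% to 13.4% of the probe sets of an array at the lower limit of 1. The software that summarised the probe sets, its background correction and its normalization are not given in the sources used here.

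The table held 45101 probe sets, of which 64 were controls. GEO's platform annotation gave 1 gene to 34958 of the others, several genes to 932 and none to 9147, and probe sets with several genes were not named. Of the named probe sets, 34754 matched the RefSeq gene table (assembly GRCm38.p6) by Entrez identifier. A gene was represented by its probe set with the highest mean over the 20 cells, which gave 18194 genes. No coordinates are given, since the files name no genome build.

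The 2%-trimmed means of the arrays ranged from 181.3 to 219.8. By a rule fixed before the data were examined, trimmed means more than 5% apart led to quantile normalization as the main setting, with the deposited values as an alternative. The analysis scale was log2(intensity + 8.75), where the pseudocount is the median over arrays of the 25th percentile, so the lowest value possible is 3.29. The floor of an array was the 95th percentile of 148 probe sets of genes of unrelated tissues and of olfactory and vomeronasal receptors, and lay between 6.34 and 7.02 on the log2 scale. Genes above the floor in at least 3 cells were tested (10238 genes). No detection calls were used, and for arrays the signal over this floor and the number of arrays limit the precision. No cell was left out. Pairs of arrays that shared most of their values numbered 0.

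Lists of markers and of functions were fixed before the data were examined, from general knowledge of blastocyst lineages, to which earlier work on such cells may have contributed. They covered epiblast, primitive endoderm, trophectoderm, general pluripotency, FGF and ERK signalling, Nodal, BMP and WNT signalling, collagen and basement membrane synthesis, endocytic and secreted endoderm proteins, epithelial adhesion and polarity, S phase, G2 and M phase, DNA methylation, glycolysis, reference, stress and dissociation, oocyte, two-cell-stage and sex genes. The rule for named genes, also fixed beforehand, took every measured lineage marker, Pou5f1, the 2 most and the 2 least variable members of each other list, the 15 genes outside the lists with the smallest variance p, and the 10 leading genes of each cluster outside the lists.

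Variances over cells were tested with limma 3.58.1 in R 4.3.3 (squeezeVar with the mean level as trend, F test, Benjamini-Hochberg at 0.05). Lists were set against 10000 random lists with each member drawn from the 50 genes nearest in mean level. Correlations used 100000 permutations, or all permutations for 8 cells or fewer, with Benjamini-Hochberg over 27 relations. A measure counted as falling into separate clusters when its widest gap over its range exceeded the 95th percentile of 10000 normal samples, or when the BIC of mclust 6.1.1 favoured 2 components by over 6. Cells were clustered by Ward's method on profiles centred per gene and standardised per cell, with the number of clusters from 2 to 5 that gave the highest silhouette (scipy 1.17.1, scikit-learn 1.9.0). The plan was to cluster on the genes past the variance threshold. As 0 genes passed, a set planned beforehand as another setting, the 500 genes with the largest variance ratio without list genes, was used for the reported clustering. A cluster was named from the fixed markers only. Among the 10 genes with the largest difference, the epiblast-like cluster had 2 epiblast markers (Fgf4 and Klf2) and 0 of the other lineages, and the primitive endoderm-like cluster had 7 primitive endoderm markers and 0 of the others. Doublets were not called, since cells were picked singly.

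The steps were tested on simulated data of 20 cells, with the same 10238 genes for the variance and list tests. With gene variances equal to the trend, the variance test called 112 of 200 genes whose variance was raised 4 times (56%) and 188 of 200 raised 16 times (94%), with 5 and 0 other genes called. With variances as spread out as limma's fitted prior, it called 0 and 1 of the 200, with 3 and 2 other genes called, so a count of 0 there says little about which genes vary. The coordination test called 39 of 40 coordinated lists and 9 of 200 null lists at an unadjusted p under 0.05, and the spread test called 10 of 200 null lists. A correlation of 0.7 over 20 cells was called in 194 of 200 simulations and a correlation of 0 in 13. Simulated clusters of 10 cells, over 500 independent genes of which a part was shifted by more than its SD, were recovered in 20 of 20 simulations. Cells without clusters were not simulated. As the rule always returned at least 2 clusters, the test does not show that it would find none.

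The alternatives were pseudocounts from the 10th and 50th percentiles, deposited values, no filter or a filter of 10 cells, a floor at the 99th percentile, the mean of all probe sets of a gene, a robust limma prior, random lists from 200 neighbours, correlations without the 2 farthest cells or with standardised scores, 2000 genes for the clustering, and average linkage or k-means. Added after the data were seen were leaving out cell 19, the chi-square test, clustering with the list genes kept, and clustering on all tested genes outside the lists. The percentiles of list differences between the clusters, the bounds, the comparison of controls with genes of their level, the correlations within the clusters of cells, the SDs without 1 cell, the mitotic genes without 4 cells, the differences, list percentiles and leading genes with values raised to the floor, and the genes found in 1 cluster were also added then.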

Results

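Transcript levels were measured in 20 single cells from the inner cell mass of C57BL/6 mouse blastocysts at embryonic day 3.5. The inner cell mass is the group of cells inside the blastocyst that gives rise to the epiblast, the source of the embryo proper, and to the primitive endoderm, an extraembryonic layer. Per the series design, 55 cells were picked at random after trypsin dissociation, and 50 of them were positive for Oct4 (Pou5f1) and negative for the trophectoderm gene Cdx2 in a PCR screen of the amplified cDNA. Each of the 20 arrays held the cDNA of 1 cell, and all 20 formed 1 group, so the design held no comparison between groups. The question open to these data was how far the cells differed from one another, and in which genes. Cells are named by their replicate number. The labels did not tie cells to embryos, so the p-values below cover only these 20 samples, and no p-value was computed between clusters of cells. Those of correlations and exact tests come from the cells. Those of list tests come from random gene lists over the same cells, and those of the variance test from a prior fitted over genes. List and variance tests therefore compare genes with other genes, as if genes were exchangeable. The median deposited intensity per array was 14.97 in cell 19 and lay between 25.56 and 30.14 in the others. Between 26.3% and 32.4% of probe sets per array were above a floor set from genes of unrelated tissues. This share follows from the array's floor alone, as quantile normalization gave the arrays a common distribution. Pearson's r between pairs of cells over genes ranged from 0.554 to 0.756 (genes are not independent replicates). The number of arrays limits the precision of every value.

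The 20 cells fell into 2 groups of 10 that carried opposite lineage markers. The clustering used 500 variable genes and none of the genes in the lineage lists. In 1 cluster Fgf4, Klf2, Nanog and Sox2 were high, and it is called epiblast-like (cells 1, 2, 7, 9, 12, 13, 14, 16, 18 and 19). In the other Gata4, Gata6, Sox17, Pdgfra and Cubn were high, and it is called primitive endoderm-like (cells 3, 4, 5, 6, 8, 10, 11, 15, 17 and 20). The epiblast score, the mean of 13 markers centred per gene, was 1.26 ± 0.73 (SD, n = 10 cells) in the epiblast-like cluster and -1.26 ± 0.76 in the primitive endoderm-like cluster on the log2 scale. The primitive endoderm score, from 17 markers, was -1.5 ± 0.63 and 1.5 ± 0.43. No cell of either cluster reached the range of the other on either score. By the rule for separate clusters of values, the primitive endoderm score separated (widest gap over range 0.261, limit 0.225). The epiblast score did not (0.111), and neither did Nanog (0.158) or Gata6 (0.194). Among 10000 random lists matched on mean level, the median member difference of the epiblast markers (2.23) lay at percentile 100, above every random list, and that of the primitive endoderm markers (-2.94) at percentile 0. The epiblast median is the difference of Otx2, which was below the floor in most cells. With values under the floor of each array raised to it, the medians were 1.12 and -2.23, at the same percentiles. The mean silhouette was 0.101 for 2 clusters and 0.0662 for 3, which is a weak separation over the 500 genes. Cell 16 changed sides under 6 alternative settings.

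**Figure D1:**
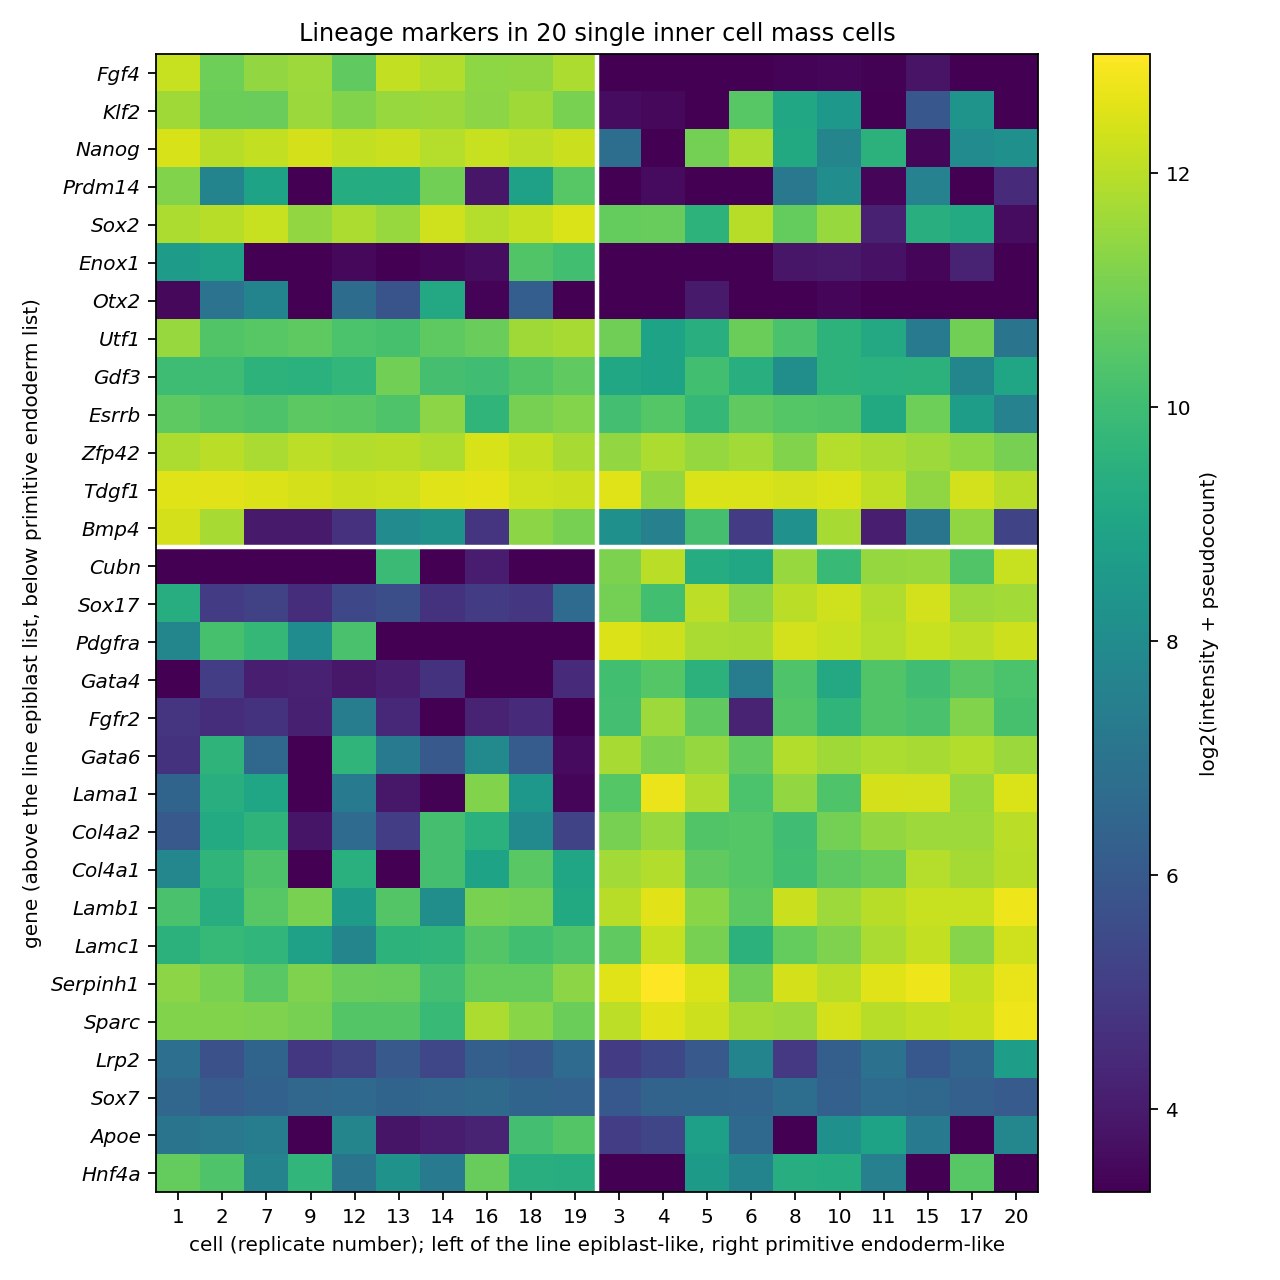
Log2 intensity of each tested epiblast marker (above the white horizontal line) and primitive endoderm marker (below it) in the 20 cells, with epiblast-like cells left of the vertical line and primitive endoderm-like cells right of it; columns are cells and colour is log2(intensity + pseudocount). Fgf4 lay above the floor in the 10 cells on the left only and Gata4 in the 10 cells on the right only.

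**Figure D2:**
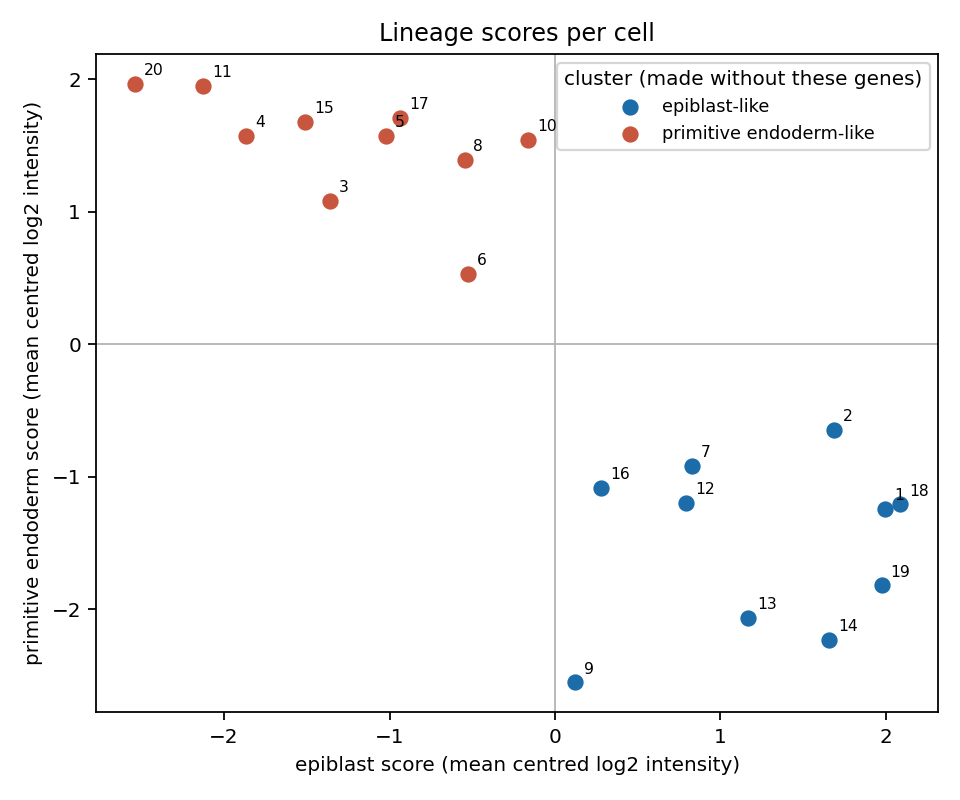
Epiblast score (x axis) against primitive endoderm score (y axis), each the mean of centred log2 intensities, with 1 point per cell labelled by its number and coloured by cluster. The epiblast score ran from 0.12 to 2.09 in the epiblast-like cells and from -2.54 to -0.16 in the primitive endoderm-like cells.

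All 13 tested epiblast markers had the higher mean in the epiblast-like cluster, 6 of them at least 2-fold (Nanog, Sox2, Fgf4, Klf2, Prdm14 and Utf1). Otx2 and Enox1 were above the floor in 3 and 4 epiblast-like cells and in 0 others, too dim for a fold. Fgf4, a secreted growth factor, was above the floor in 10 of 10 epiblast-like cells (11.54 ± 0.51, log2, SD) and in 0 of 10 primitive endoderm-like cells (3.37 ± 0.16). Set against the floor of each array, its level was at least 28.5-fold higher. Where no cell of a cluster was above the floor, folds are such bounds. Elsewhere the means and differences include values under the floor as read, so those of genes mostly under the floor in 1 cluster depend on the pseudocount and are not conservative. Of 65 named genes with cells above the floor in both clusters and a difference of at least 1, 31 had a difference over 1.5 times smaller with values raised to the floor. It was then 3.65 for Klf2, 2.09 for Prdm14, -4.62 for Sox17, -4.23 for Pdgfra, -4.06 for Gata6 and -3.68 for Lama1. The transcription factor Nanog was even across the epiblast-like cells (12.17 ± 0.16) and ranged widely in the primitive endoderm-like cells (7.90 ± 2.82), where 8 of 10 cells were still above the floor. Klf2, a pluripotency transcription factor, was 11.31 ± 0.31 against 5.93 ± 2.89, Sox2 was 11.96 ± 0.33 against 9.17 ± 2.92, and Prdm14 was 8.39 ± 2.74 against 4.75 ± 2.02. The smallest differences were those of Bmp4 (0.14, with an SD of 2.65 between primitive endoderm-like cells) and Tdgf1 (0.27, SD 0.43), both within the spread between cells, and that of Bmp4 was -0.19 without cell 19. The differences of Sox2 (2.79), Utf1 (1.38, SD 1.41), Esrrb (0.77, SD 1.03) and Enox1 (2.265, SD 3.18) were also smaller than the larger SD of the clusters. Sox2 was lowest in cells 11 and 20 (4.17 and 3.62). Nodal was above the floor in 0 of 20 cells. With the mean of all probe sets of a gene in place of the brightest, the difference was -2.65 in place of -5.07 for Gata6 and -1.74 for Fgfr2. By the brightest probe set Fgfr2 was above the floor in 9 primitive endoderm-like cells and 1 epiblast-like cell, and differed by -3.28 with values raised to the floor.

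Of 17 tested primitive endoderm markers, 14 had the higher mean in the primitive endoderm-like cluster, 13 of them at least 2-fold by the brightest probe set. Lamc1, counted among them at -1.70, differed by -0.74 with the mean of all probe sets. Its other probe set, above the floor in 19 cells, differed by 0.22. Gata4, an endoderm transcription factor, was above the floor in 10 of 10 primitive endoderm-like cells (9.82 ± 0.96) and in 0 of 10 epiblast-like cells, where its bound gave a level at least 8.46-fold lower. Gata6 was 11.55 ± 0.40 against 6.48 ± 2.23, Sox17 11.63 ± 0.69 against 5.64 ± 1.44, and the receptor gene Pdgfra 12.13 ± 0.24 against 6.24 ± 3.22. The endocytic receptor gene Cubn was above the floor in 10 primitive endoderm-like cells (10.85 ± 1.12) and in 1 epiblast-like cell. It differed by 3.78 log2 units with values under the floor raised to it. The basement membrane genes Lama1 (11.58 ± 0.95 against 6.59 ± 2.94), Col4a1 (11.18 ± 0.72 against 8.25 ± 2.73), Lamb1 (11.94 ± 0.65 against 9.95 ± 1.07) and Sparc (12.17 ± 0.36 against 10.92 ± 0.55) went the same way. Hnf4a, a nuclear receptor gene of the visceral endoderm and liver, went the other way, with 9.05 ± 1.41 in the epiblast-like and 6.61 ± 2.99 in the primitive endoderm-like cluster. That difference was within the spread between cells, and was 1.045 with values raised to the floor. Apoe (6.52 against 6.46) and Sox7 (6.44 against 6.40) did not differ by more than their spread. Ttr and Afp were above the floor in 0 cells by any probe set and Dab2 in 0 cells by the probe set used here and in 1 cell by each of 2 others, Amn and Bmp2 in 1 cell and Foxa2 in 2.

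Genes of the trophectoderm, the outer layer of the blastocyst, showed no common direction between the clusters. Tfap2c had the higher mean in the epiblast-like cells (8.88 ± 2.99 against 6.68 ± 3.06, within the spread between cells), and Lgals3 was above the floor in 5 epiblast-like and 0 primitive endoderm-like cells, at least 1.38-fold higher. Eomes (7.12 ± 2.32 against 5.42 ± 2.14), Krt8 (7.41 ± 2.22 against 5.81 ± 2.55) and Tead4 (7.57 ± 1.53 against 6.49 ± 2.27) had the higher mean in the primitive endoderm-like cells, each within the spread between cells. The trophectoderm score was 0.02 ± 0.59 in the epiblast-like and -0.02 ± 0.30 in the primitive endoderm-like cluster, and its median member difference lay at percentile 14.97 of matched random lists. That median (-0.07) is the difference of Hand1, whose probe sets disagreed. Elf5, Gata3, Krt7, Krt19 and Atp12a were above the floor in 0 of 20 cells. Eomes was above it in 9 cells, the keratin gene Krt8 in 11, Krt18 in 3 and Tfap2c in 13. The Cdx2 probe set used here read 7.43 ± 0.35 in all 20 cells, and the other Cdx2 probe set was above the floor in 0 cells. Hand1 likewise read 13.70 ± 0.08 by 1 probe set in all 20 cells and 6.03 ± 0.44 by another, which was above the floor in 1 cell, so the probe sets of Cdx2 and of Hand1 disagreed. Pou5f1, the gene the PCR screen selected for, was above the floor in 20 of 20 cells (10.85 ± 0.49), with 10.99 ± 0.35 in the epiblast-like and 10.70 ± 0.58 in the primitive endoderm-like cluster.

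Fgf4 and Fgfr2 were rarely found in the same cell, and the primitive endoderm genes occurred together. Fgf4 and its receptor gene Fgfr2 were both above the floor in 1 cell, Fgf4 alone in 9, Fgfr2 alone in 9 and neither in 1 (Fisher's exact test, two-sided, p = 0.00109, adjusted p = 0.00219 over 4 pairs). All 10 cells with Gata4 also had Sox17 (Fisher's exact adjusted p = 0.000476), Gata6 (adjusted p = 0.0145) and Pdgfra (adjusted p = 0.0325) above the floor, while Sox17, Gata6 and Pdgfra were above it without Gata4 in 1, 4 and 5 cells. Without cell 19 the Gata4 and Pdgfra pair had an adjusted p of 0.0731 by the same exact test. The counts of all these pairs rest on the brightest probe set of each gene. By other probe sets Fgfr2 was above the floor in 0 cells, Fgf4 in 10, 3 and 1, and Gata4 in 0. Gata6 was above it in 16 and 11 cells by others, Sox17 in 11 and Pdgfra in 12 and 7. Nanog and Gata6 were inversely related over the 20 cells (Pearson's r = -0.66, permutation p = 0.0015, adjusted p = 0.0203 over 27 relations, Spearman's rho = -0.82, permutation p = 3e-05, adjusted p = 0.00081). Without the 2 cells farthest from the median Nanog level, r was -0.75. With the pseudocount from the 10th percentile the call was lost (r = -0.59, permutation test, adjusted p = 0.0701). Within the clusters of cells the relation kept its sign but did not pass, with r = -0.57 over the 10 epiblast-like cells (rho = -0.47, permutation p = 0.088 and 0.181, adjusted p = 0.176 and 0.362) and r = -0.20 over the 10 primitive endoderm-like cells (rho = -0.09, permutation p = 0.598 and 0.811, adjusted p = 0.598 and 0.811). Without the 2 cells farthest from the median Nanog level, r was -0.71 in each cluster. These within-cluster values were added after the data were seen. Nanog and Gata6 were both above the floor in 12 cells, 4 epiblast-like and 8 primitive endoderm-like.

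For 8 of the 16 measures, among them the primitive endoderm score, Gata4, Fgf4, Sox2 and Klf2, the cells fell into separate clusters of values, and r was computed only within clusters of at least 6 cells. Nanog rose with Klf2 in the 14 cells with high Klf2 (r = 0.97, permutation p = 6e-05, adjusted p = 0.00162, and r = 0.90 without 2 cells), although its rank correlation did not pass (rho = 0.69, permutation p = 0.00833, adjusted p = 0.113). Nanog rose with Sox2 in the 18 cells with high Sox2 (r = 0.67, permutation p = 0.00363, adjusted p = 0.0327), while neither its rank correlation (rho = 0.52, permutation p = 0.0281, adjusted p = 0.237) nor the value without 2 cells (r = 0.63, permutation p = 0.0138, adjusted p = 0.124) passed. Nor did r pass with the pseudocount from the 10th percentile (0.64, permutation test, adjusted p = 0.0701) or with the mean of all probe sets (0.67, adjusted p = 0.0508). The cells with high Klf2 were the 10 epiblast-like cells, with Nanog between 11.93 and 12.44, and 4 primitive endoderm-like cells, with Nanog between 7.73 and 11.83. Within the epiblast-like and the primitive endoderm-like cells, in values added after the data were seen, Nanog had r = 0.31 and 0.30 with Klf2 (rho = 0.15 and 0.06, permutation p = 0.369 and 0.390 by r and 0.685 and 0.89 by rho, r = 0.44 and 0.22 without 2 cells). With Sox2 it had r = -0.54 and -0.08 (rho = -0.60 and -0.07, permutation p = 0.104 and 0.831 by r and 0.0727 and 0.864 by rho, r = -0.47 and 0.12 without 2 cells). None of these 4 relations passed, with adjusted p of 0.416 or more by r and 0.291 or more by rho. Within the 10 cells of higher primitive endoderm score, the epiblast score had r = -0.58 with it (permutation p = 0.0767, adjusted p = 0.283, rho = -0.68, permutation p = 0.0351, adjusted p = 0.237, r = -0.62 without 2 cells), which did not pass. The remaining relations of the family did not pass by r or by rho, including the S phase score with the G2 and M phase score (r = -0.04, permutation p = 0.854, adjusted p = 0.887, rho = -0.29, permutation p = 0.211, adjusted p = 0.588, r = 0.16 without 2 cells).

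Outside the lineage lists, most basement membrane synthesis and glycolysis genes were higher in the primitive endoderm-like cells. The mean score of mitotic genes was low in 4 of the primitive endoderm-like cells. The collagen and basement membrane synthesis list had a median member difference of -0.86 (epiblast-like minus primitive endoderm-like, percentile 0 of matched random lists), with 10 of 14 members higher in the primitive endoderm-like cluster. Its collagen-modifying enzyme genes Plod2 (10.40 ± 0.54 against 6.08 ± 2.75) and P4ha2 (10.61 ± 0.84 against 6.76 ± 2.73), its most variable members, had large differences. Of its least variable members, Dag1 was higher in the epiblast-like cells (10.76 ± 0.31 against 10.29 ± 0.44) and Hspg2 differed by -0.13. The glycolysis list had a median of -0.39 (percentile 0.63), with 9 of 12 members higher in the primitive endoderm-like cluster, among them the phosphofructokinase gene Pfkl (above the floor in 9 cells against 1) and Ldha (10.61 ± 1.30 against 8.50 ± 2.76, within the spread between cells). For Pfkl the difference was -2.48 with values raised to the floor. The least variable glycolysis members, Aldoa and Pgam1, differed by -0.32 and -0.07. Of 23 G2 and M phase genes, 20 were higher in the epiblast-like cluster (median 0.82, percentile 100, and 0.50 at the same percentile with values raised to the floor). Top2a, which untangles DNA before division, was 11.78 ± 0.28 against 9.55 ± 3.12 (within the spread between cells), and Ube2c, a mitotic ubiquitin-conjugating enzyme gene, was 12.27 ± 0.44 against 10.48 ± 1.78. These were the most variable members. The least variable, Birc5 and Ccnb2, differed by -0.08 and -0.10. The G2 and M phase score was 0.54 ± 0.44 in the epiblast-like cells and -0.54 ± 1.23 in the primitive endoderm-like cells, whose values ran from -2.87 to 0.79, so the clusters overlapped. Cells 4, 8, 17 and 20, the 4 primitive endoderm-like cells with a score under -1, also had the lowest mean correlation with the other cells. Without them, in values added after the data were seen, the score was 0.31 ± 0.40 in the other 6 primitive endoderm-like cells, 14 of 23 members were higher in the epiblast-like cluster, and the median was 0.13 (percentile 89.8). As these cells were left out for their low score of the same genes, a smaller difference was fixed in advance and is a description only. Top2a was then 11.78 against 11.07 ± 0.71 and Ube2c 12.27 against 11.67 ± 0.44. The lys control probe set, read on the same arrays, was 12.61 ± 0.12 and 12.75 ± 0.13 in these clusters.

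In several other lists a few members differed strongly while the list's median stayed near 0, and in some the mean lay farther from 0 than the median. Dnmt3l, a cofactor of the de novo DNA methyltransferases, was 10.95 ± 0.85 in the primitive endoderm-like and 6.83 ± 2.79 in the epiblast-like cluster, but the DNA methylation list had a median of 0.04 (percentile 49.2) and a mean of -0.57 (percentile 0.18, or -0.30 and 1.43 with values raised to the floor). Dusp4, a phosphatase that acts on ERK, was above the floor in 8 primitive endoderm-like and 0 epiblast-like cells, at least 3.92-fold higher, and the FGF and ERK list had a median of 0.03 (percentile 47.0) and a mean of -0.34 (percentile 2.18, or -0.09 and 15.2 with values raised to the floor). The RNA-binding protein gene Lin28a was above the floor in 7 primitive endoderm-like and 0 epiblast-like cells, at least 1.55-fold higher, and the general pluripotency list had a median of 0.03 (percentile 68.6) and a mean of -0.04 (percentile 23.97). In the epithelial adhesion and polarity list (median 0.24, percentile 94.2, mean 0.89, percentile 99.95, or 0.34 and 98.9 with values raised to the floor) the polarity genes Pard6b (8.13 ± 1.92 against 4.31 ± 2.21) and Prkcz (8.55 ± 1.27 against 5.62 ± 2.55) were higher in the epiblast-like cells (Prkcz differed by 0.12 with the pseudocount from the 10th percentile), while Cdh1, E-cadherin, was higher in the primitive endoderm-like cells (11.76 ± 0.19 against 11.30 ± 0.23). The medians of the S phase (-0.02, percentile 22.2), reference (-0.02, percentile 18.6), stress (0.12, percentile 76.5), endocytic and secreted endoderm (-0.06, percentile 29.7) and Nodal, BMP and WNT (-0.17, percentile 3.93) lists were small.

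The genes outside every list with the largest mean differences are what define the clusters and are given as a description only, ranked by values as read. For the epiblast-like cluster they were Atg16l2, Khdc1a, Nipal1, Slc7a3, Mymx, Spic, Apela, Ggct, Rhpn2 and Bcl2l14, with differences from 2.10 (Ggct) to 3.13 (Spic) log2 units when values under the floor were raised to it. For the primitive endoderm-like cluster they were Sdc4, Pth1r, Rap2c, Flrt3, Emb, Slc46a3, Dkk1, Havcr1, Aqp8 and Dcaf12l1, from -1.64 (Slc46a3) to -4.05 (Sdc4) in the same way. Which genes lead depends on the pseudocount, as most cells of the lower cluster were below the floor for many of them. Ranked with values raised to the floor, 6 and 5 of these 10 genes each stayed among the 10 largest, and the 10th of those differed by 2.54 and 2.57. For Atg16l2 the unraised difference was 5.64, 7.30 with the pseudocount from the 10th percentile and 3.61 with the mean of all probe sets. Slc7a3, an amino acid transporter gene, was above the floor in 8 epiblast-like and 0 primitive endoderm-like cells.

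Over all 20 cells, the lineage markers and the mitotic genes were the lists whose members rose and fell together most. Coordination, the variance of a list's mean over the mean variance of its members, was 0.413 for the G2 and M phase genes, 0.409 for the primitive endoderm markers and 0.381 for the epiblast markers, against medians of 0.0452, 0.0593 and 0.0763 for random lists of the same levels (one-sided resampling, adjusted p = 0.000567 for each over 17 lists, the smallest that 10000 random lists can give here). Without cells 4, 8, 17 and 20, which were chosen by their low score of the same genes, that of the G2 and M phase genes was 0.172 (median of random lists 0.0434, one-sided resampling p = 0.0001). Coordination was also above that of random lists for collagen and basement membrane synthesis (0.177, adjusted p = 0.00382), epithelial adhesion and polarity (0.140, adjusted p = 0.00646) and glycolysis (0.158, adjusted p = 0.0261). The other 11 lists did not pass, among them the trophectoderm markers (0.0782, adjusted p = 0.594), the S phase genes (0.0849, adjusted p = 0.176), the stress and dissociation genes (0.113, adjusted p = 0.334) and the reference genes (0.0952, adjusted p = 0.594). The epithelial result did not pass under 2 alternative settings.

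**Figure D3:**
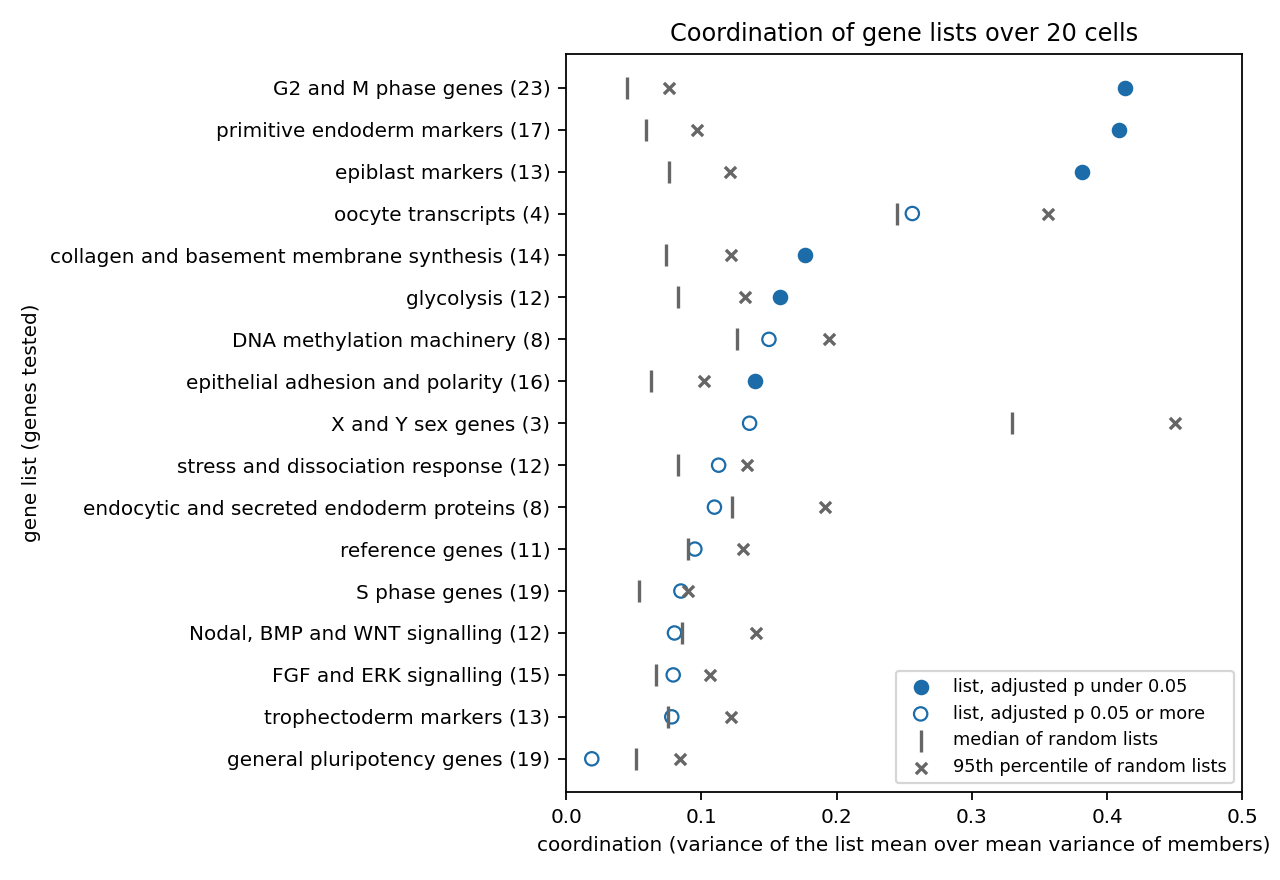
Coordination of each gene list over the 20 cells (x axis, variance of the list mean over the mean variance of its members; circles), with the median (bars) and 95th percentile (crosses) of 10000 random lists matched on mean level; filled circles have an adjusted p under 0.05 and the number of tested genes stands in parentheses. The G2 and M phase genes, the primitive endoderm markers and the epiblast markers lie at 0.413, 0.409 and 0.381.

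The spread of a list, its members' SD over the SD of the level trend, exceeded that of matched random lists by 2.54 times for the primitive endoderm markers (two-sided resampling, adjusted p = 0.00113 over 17 lists), 2.41 times for the X and Y sex genes (adjusted p = 0.00113, not past the threshold with the mean of all probe sets), 1.91 times for the epiblast markers (adjusted p = 0.00453) and 1.72 times for the G2 and M phase genes (adjusted p = 0.00113). It also did so for FGF and ERK signalling (1.77 times, adjusted p = 0.00453), general pluripotency genes (1.52 times, adjusted p = 0.00453), DNA methylation machinery (1.48 times, adjusted p = 0.0225) and epithelial adhesion and polarity (1.46 times, adjusted p = 0.0204), which each lost the call under at least 1 alternative setting. The FGF and ERK list reversed to a log2 spread of -0.0091 with the mean of all probe sets. The 9 remaining lists did not pass, with the reference genes at 0.988 times (adjusted p = 0.953), the trophectoderm markers at 1.35 times (adjusted p = 0.306) and the stress and dissociation genes at 1.29 times (adjusted p = 0.341). No member of the two-cell-stage list passed the filter.

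Gene by gene, limma's test of each variance against its level trend called 0 of 10238 genes. At an unadjusted p under 0.05 it gave 30 genes, where 511.9 are expected by chance, and the smallest adjusted p was 0.727. Adjusted over the list alone, 0 genes were called in each of the 17 lists. The fitted prior had 2.08 degrees of freedom, so that the variances of genes of 1 level were themselves widely spread. A chi-square test that took the trend as exact, added after the data were seen, called 5550 genes (54.2%). The genes outside the lists with the smallest p were Hipk2 (11.80 ± 2.01, n = 20), Asns, the asparagine synthetase gene (11.03 ± 2.14), Bhmt (11.87 ± 1.17) and Cks2 (12.24 ± 0.81), followed by Trim43a, Tfrc, Creg1, Manf, Inhbb, Mt1, Rcn1, Dusp14, Dcaf12l1, Flrt3 and Khdc1a. For 3 of these 15 genes the SD fell by more than 1.5 times without the farthest cell, a test added after the data were seen. Without cell 5, where Hipk2 was at the lower limit (3.29), its SD was 0.17. Without cell 20 that of Creg1 was 0.46 in place of 1.72, and without cell 10 that of Manf was 0.87 in place of 1.86.

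Control transcripts also varied between cells. The lys control probe set read 12.68 ± 0.14 (log2, SD, n = 20), dap 9.84 ± 0.65, and phe 8.20 ± 0.90 with 19 cells above the floor, while thr was above the floor in 3 cells by this 3′ probe set, in 5 by the middle one and in 2 by another 3′ probe set. The labels do not say whether such RNA was added to the lysates, nor in what amount. Of the genes within 0.25 log2 units of the lys, dap and phe levels, 53.6% of 69, 77.8% of 608 and 74.4% of 829 had a larger SD than that 3′ probe set. At the lys level the control's SD was close to the genes' median SD of 0.15. The middle and 5′ probe sets of phe had SDs of 1.41 and 1.98, with 15 and 6 cells above the floor. The hybridization control CreX read 12.90 ± 0.08 and BioB 8.28 ± 0.25. For Gapdh the SD was 0.11 at the 3′ probe set, 0.26 at the middle and 0.93 at the 5′ probe set, and for Actb 0.46, 1.03 and 0.62.

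Xist and the Y-linked genes were each found in cells of both clusters. Xist, the RNA that coats the inactive X chromosome, was above the floor in 5 cells, 2 epiblast-like and 3 primitive endoderm-like. The Y-linked genes Eif2s3y and Kdm5d were above the floor in 12 and 8 cells, and 14 cells had at least 1 of them, 8 epiblast-like and 6 primitive endoderm-like. Eif2s3y was 7.44 ± 2.72 in the epiblast-like and 6.36 ± 3.17 in the primitive endoderm-like cells, and Kdm5d 6.29 ± 2.66 and 5.07 ± 2.46, within the spread between cells. The list of 3 sex genes had a median difference of 1.08 (percentile 97.1 of matched random lists), or 0.31 (percentile 96.4) with values raised to the floor. No cell had Xist and a Y-linked gene above the floor, and cell 17 had none of the 3.

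**Figure D4:**
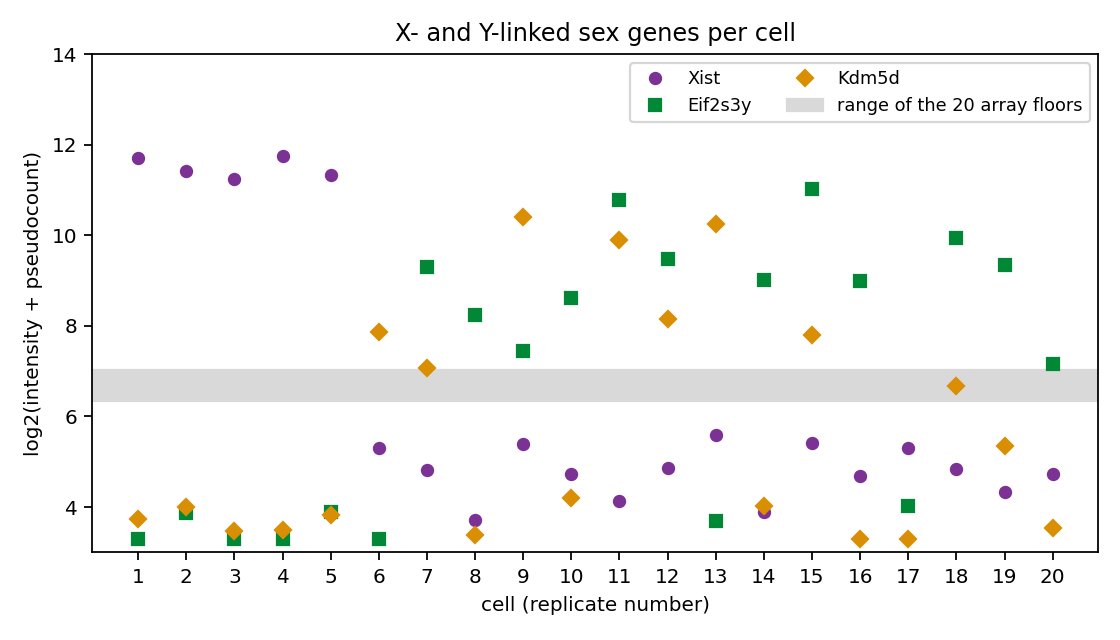
Log2(intensity + pseudocount) of Xist, Eif2s3y and Kdm5d (y axis) in each of the 20 cells (x axis), with 1 marker per gene and cell and the range of the array floors in grey. Xist lies above the floor in 5 cells, and in none of these does a Y-linked gene.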

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

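Of 706 values recomputed under the alternatives, 676 kept their side of the threshold or stayed close. Values past the threshold under neither setting were counted among these even where their sign changed. The log2 spread of the trophectoderm markers, for example, was 0.43 and became -0.62 with the mean of all probe sets. The alternatives without cell 19, the chi-square test, and clustering with list genes kept or on all genes were chosen after the data were seen. The cause of the changes below was not tested. The variance test called 0 genes with the robust prior and 5550 with the chi-square test, which by construction takes the trend as exact. With the pseudocount from the 10th or the 50th percentile, a filter of 10 cells, a floor at the 99th percentile, 2000 genes, or all genes outside the lists, 19 of 20 cells kept their cluster (cell 16 moved), and with no filter 18 did (cells 6 and 10 moved), where the primitive endoderm score differed by -2.06. Log2 spreads no longer past the threshold were as follows. Pluripotency fell to 0.39 and the sex genes to 0.90 with the mean of all probe sets, where FGF and ERK reversed to -0.0091. FGF and ERK gave 0.57 with a filter of 10 cells and 0.29 with the floor at the 99th percentile. The epithelial list gave 0.50 with the 10th percentile, 0.52 with a filter of 10 cells and 0.23 with the mean of probe sets, and its coordination 0.109 and 0.123 under the 10th percentile and the filter. DNA methylation gave 0.56 and 0.52 with the 10th and 50th percentiles, 0.44 with no filter, 0.51 with the filter, 0.35 with the 99th percentile and 0.11 with the mean of probe sets. Nanog with Gata6 had r = -0.59 with the 10th percentile, and Nanog with Sox2 had r = 0.64 there, 0.67 with the mean of probe sets and 0.63 without 2 cells, none past the threshold. Gata4 and Pdgfra shared 10 cells without cell 19, no longer past it. Of 1168 values for 146 named genes, 20 moved by more than their spread. The sign changed in 16 values of 15 genes, with reported differences of up to 0.78 (Hipk2), of which Dag1 (-0.0166 with the mean of probe sets) alone had a reported difference beyond its spread, and Hand1 went to 0.04 with deposited values. Clustering on genes past the threshold, with or without list genes, was not run, since 0 genes passed. Signal over the floor limits dim genes, for which only bounds are given.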

Other observations

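All tests in this part were chosen after the results were seen. Some cells carried markers of both lineages. Cell 6, in the primitive endoderm-like cluster, had the lowest primitive endoderm score of its cluster (0.53), with Nanog at 11.83, Sox2 at 11.99 and Klf2 at 10.49 beside Gata6 at 10.63, Sox17 at 11.31 and Pdgfra at 11.76, and neither Fgf4 (3.29) nor Fgfr2 (4.24) above the floor. Cell 12, in the epiblast-like cluster, had Fgf4 at 10.64 together with Fgfr2 at 7.43, Gata6 at 9.67 and Pdgfra at 10.21. Cells 9 and 16 had the lowest epiblast scores of their cluster (0.12 and 0.28). These cells were singled out after their values were seen.

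The egg coat gene Zp3 was above the floor in 8 of 10 epiblast-like and 0 of 10 primitive endoderm-like cells (7.63 ± 1.82, SD, at least 1.89-fold higher). Ooep, a maternal factor of the egg, was 10.42 ± 0.89 against 8.53 ± 2.12, within the spread between cells. The oocyte list as a whole (4 tested genes) had a median difference of 0.89 (percentile 97.0 of matched random lists), or 0.74 (percentile 99.8) with values raised to the floor. Of its members, Gdf9 (6.40 against 6.64) and Nlrp5 (5.19 against 5.31) were near or below the floor. Hnf4a had the lower mean in the primitive endoderm-like cluster by both of its brighter probe sets, with differences of 2.44 and 1.71. The first was within the spread between cells and was 1.045 with values raised to the floor. Pmaip1, an apoptosis gene, was 9.38 ± 3.36 in the primitive endoderm-like and 6.86 ± 3.27 in the epiblast-like cluster, less than the spread between cells.

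The split into an epiblast-like and a primitive endoderm-like cluster was set against technical and other explanations. Sex of the embryo as the whole cause is argued against, since the cluster with fewer Xist-expressing cells still held 2 of the 5. Loss of transcripts in 1 cluster through poorer cDNA or arrays would lower both kinds of marker there, and is argued against as the cause in the lineage markers. With values raised to the floor, the median difference was -2.23 for the primitive endoderm markers and 1.12 for the epiblast markers, each beyond all 10000 random lists, and Fgf4 and Gata4 were at least 28.5-fold and 8.46-fold apart in opposite directions. For the other genes it stays open. Of 9519 genes outside the lists and the clustering set, 0 were found in at least 8 cells of a cluster and at most 2 of the other with a 4-fold difference in deposited values, in either direction or in 99 other splits, so that test decided nothing. Amplification that favoured some genes in some cells was not tested. Of 4 quality measures 1 differed between the epiblast-like and the primitive endoderm-like cluster by more than the larger SD. That was the lys level, 12.61 ± 0.12 and 12.75 ± 0.13. The others were the percent of probe sets above the floor (28.7 ± 1.70 and 29.0 ± 1.68), the mean correlation with the other cells (0.671 ± 0.0125 and 0.650 ± 0.0251) and the 5′ probe set of Gapdh (10.27 ± 1.13 and 10.82 ± 0.61). After quantile normalization the percent above the floor depends on each array's floor alone, so it cannot show a loss of transcripts. Embryo of origin stays open, since the labels name the embryo of 0 cells. Apart from sex, no biological explanation was tested, as the design names no group.

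As a list, the G2 and M phase genes were low in some primitive endoderm-like cells, with scores of -2.87 in cell 4, -2.05 in cell 8, -1.24 in cell 20 and -1.10 in cell 17. Not every member was low in each of them. Ccnb2, with a mean of 10.92 over the 20 cells, read 11.06, 10.14, 11.50 and 10.68 in these cells, in that order. Birc5, with a mean of 11.03, read 10.28, 10.76, 11.49 and 10.73. Over the 20 cells the score rose with the cell's mean correlation with the other cells (r = 0.84, permutation p = 2e-05, adjusted p = 6e-05 over 3 relations, rho = 0.68, permutation p = 0.00141, adjusted p = 0.00423, r = 0.80 without 2 cells, and 0.42 and 0.87 within the epiblast-like and the primitive endoderm-like cells, permutation p = 0.221 and 0.00158), so cells low in mitotic genes also differed most from the rest. Whether fewer transcripts were detected in cells 4, 8, 20 and 17 was not settled. In deposited values, not tested further, these cells had 12.26%, 11.68%, 12.54% and 13.44% of probe sets at the lower limit (median of all cells 11.3%). Their median intensities were 25.56, 26.72, 26.11 and 25.83 (28.4). These values lean toward fewer transcripts. Yet epiblast-like cells 9, 13 and 19, with scores of 0.09, 0.69 and 0.89, had 12.38%, 11.81% and 13.1%, and intensities of 25.96, 26.86 and 14.97. The percent of probe sets above the floor, used for the test, depends on the array's floor alone after quantile normalization. Its r with the score was 0.19 (permutation p = 0.426, adjusted p = 0.426, rho = 0.31, permutation p = 0.186, adjusted p = 0.186, r = -0.08 without 2 cells). Less RNA in these cells beside the lys control may contribute, as r with the lys level was -0.61 (permutation p = 0.00335, adjusted p = 0.00502), but the relation did not pass by rank (rho = -0.45, permutation p = 0.0454, adjusted p = 0.0682) or without 2 cells (r = -0.48, permutation p = 0.0446, adjusted p = 0.0669), r was -0.10 and -0.66 within the clusters (permutation p = 0.801 and 0.041), and the labels do not say that the control was added. A difference in cell cycle phase was not tested, and the reference gene score fell into separate clusters and was given no pooled r.

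The 5 cells with Xist above the floor carried the numbers 1 to 5, which was noticed in the data. The labels do not say what the numbering follows, and no explanation was tested. Cells 1 and 2 were epiblast-like and cells 3, 4 and 5 primitive endoderm-like.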
